A study of Mus musculus with 12 samples.

How the data were processed

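Poly(A)-selected, stranded RNA-seq libraries were made from cardiac samples, per the labels' protocols. Reads were processed with TopHat2 and Cuffdiff against mm10, per the submitters' processing notes, and their versions and settings are not given in the sources used here. The 4 tables used were comparisons at gene and isoform level, and their group values are FPKM (fragments scaled to transcript length and to the number of mapped fragments) as deposited by the authors, 1 per group. Per the file headers, each row also held a status, a log2 fold change, a test statistic (a score with no fixed range), a p-value and a q-value, all deposited by the authors. Depth per sample is unknown, and the replicates enter only through the authors' own test. All deposited p-values were whole multiples of 5e-05, their smallest value. The normal deviate of the deposited p was 1.74 times the deposited test statistic (median over 10143 genes at 7 weeks), close to the square root of 3, 1.73. A test built on the statistic alone is therefore more conservative, and its counts are given as an alternative.

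Groups were taken from the labels. Fold changes were recomputed as the log2 ratio of the 2 deposited FPKM values, because some cells of the deposited fold column did not hold a number, and no pseudocount was added. Some gene symbols in the deposited tables had been turned into dates (27 rows of each gene table), and these were left as they stood. Rows that join several symbols (15 tested in each gene table) were not named. The 7wkKO values of the 2 gene tables differed by a median of 0.779% over the 11510 genes with FPKM over 1 in both, and by other amounts for single genes (Acta1 was listed at 1755 and 1764). Hba-a2, which was not tested by the authors, was listed at 0.0163 in 1 table and at 46.2 in the other for the same 7wkKO samples. Levels in 9wkKO relative to 7wkWT were set as the sum of both log2 folds, each taken within its own table, and no deposited test applies to them. Where an error is given for such a level, it combines the errors of both folds implied by the deposited statistics alone. File starts were raised by 1 to give positions as a genome browser shows them. These positions are loci of the deposited table and can span more than the gene's annotation.

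A gene or isoform was called at a deposited q under 0.05 with the authors' status OK. For 36 gene lists fixed before the data were examined, the median log2 fold of the tested members was placed among 10000 random lists matched on mean FPKM in 20 bins, calls were compared with other tested genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists, and deposited p-values were adjusted over the list alone. Mitochondrially encoded transcripts were not analysed here. The named genes followed a rule fixed before the data were examined. It took Egfr, its family and Ppp2r3a, a set of cardiac genes, the 10 largest rises and falls with FPKM of at least 1 in both groups, up to 4 called members of each list described or the 2 most abundant where none was called, and the 5 largest changes for each combination of directions. A gene that this rule selects is not reported here. The relation between comparisons was set beside 200 simulations with no effect, with the variance implied by the deposited p shared equally between the 2 groups of a comparison. Genes with an implied standard error over 0.5 were left out of it. That limit was chosen after seeing the data, because a few genes with extreme implied errors dominated a first simulation.

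The calculations were tested on simulated data. With 200 genes changed by a log2 fold of 1 among 11609, 91.5% were recovered for the 7 week comparison, with 8 unchanged genes called, and among 11678 genes 89.0% were recovered for the later comparison. The simulated noise and the simulated calls used the same errors, those implied by the deposited p. These percentages check the calculation and do not measure how many changes the deposited calls would find. A covariance of -0.02 put into 11544 simulated genes was recovered as -0.0194. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. The alternatives were other thresholds on q, a fold minimum, FPKM filters, recomputed adjustment, the statistic alone, isoform calls, centring, pseudocounts, unmatched random lists and other shares of the variance. Leaving out single replicates and regrouping samples were not possible, because the tables hold no value per sample.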

Results

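RNA-seq was performed on cardiac samples of mice labelled wild type or epidermal growth factor receptor (EGFR) knockout at 7 and 9 weeks of age. EGFR is a receptor tyrosine kinase, and the study title names PR72, a regulatory subunit of protein phosphatase 2A (PP2A) encoded by Ppp2r3a. The 12 samples formed 4 groups of 3, here called 7wkWT, 7wkKO, 9wkWT and 9wkKO. The authors' deposited tables used here compared 7wkKO with 7wkWT and 9wkKO with 7wkKO, and the 9wkWT samples were not analysed here. Each table held 1 FPKM value per group and none per sample. The spread between replicates and the depth per sample are therefore unknown, and no SD accompanies any value below. Nothing in the labels says that the samples of a group came from separate animals. All FPKM, fold, p and q values below are those of the authors' deposited tables, with folds recomputed as the log2 ratio of the 2 group values, and a gene is called changed where the deposited Cuffdiff q was under 0.05.

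The targeted gene was examined first. In the authors' deposited table, Egfr (mm10, chromosome 11, 16752203 to 16913907) was listed at FPKM 1.20 in 7wkWT and 1.64 in 7wkKO, a log2 fold of 0.46 with a deposited p of 0.0364 and q of 0.379. It was listed at 1.59 in 9wkKO, and its log2 fold from 7 to 9 weeks was -0.06 (deposited q = 0.991). The Egfr level was thus not lower in the samples labelled knockout. The part of the gene that was deleted is not given in the sources used here, so a level over the whole gene does not check the label, and all directions below refer to the samples labelled knockout. The related receptor gene Erbb3 rose from 1.10 to 1.94 in 7wkKO in the authors' deposited table (log2 fold 0.82, q = 0.0314). Hbegf, which encodes a ligand of EGFR, rose from 9.56 to 14.5 (log2 fold 0.60, q = 0.0124). Erbb2 had FPKM of 3.20 and 3.06 (q = 0.989), and Erbb4, at 0.254 and 0.758, was not tested by the authors. Of 7 tested genes in the list of family receptors and ligands, which also holds Errfi1, neither of these, 2 were called higher and 5 were not called. At an unadjusted p under 0.05 there were 4, all higher, and 2 passed when adjusted over the list alone. The log2 fold was above 0 for 6 of 7, with a median of 0.46 at the 99.98th percentile of matched random lists (adjusted Fisher's exact p = 0.0616). From 7 to 9 weeks 0 of the 7 passed the deposited Cuffdiff test, with 1 at an unadjusted p under 0.05.

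Ppp2r3a (chromosome 9, 101104989 to 101251832) did not pass the threshold in either comparison. In the authors' deposited table its FPKM was 72.5 in 7wkWT and 65.2 in 7wkKO (log2 fold -0.15, p = 0.313, q = 0.833). The later comparison listed it at 65.7 in 7wkKO and 49.7 in 9wkKO in the authors' deposited table. The log2 fold there was -0.40, with a deposited Cuffdiff p of 0.0038 and q of 0.0723. The isoform table listed a shorter product of 530 codons (NM_172144) and a longer one of 1150 codons (NM_001161362). The shorter isoform made up 91.5% of the summed isoform FPKM in 7wkWT, 91.8% in 7wkKO and 89.5% in 9wkKO in the authors' deposited tables. Its FPKM was 66.3 in 7wkWT and 59.9 in 7wkKO (q = 0.866), and it was 60.3 in 7wkKO and 44.5 in 9wkKO in the other comparison. The later log2 fold was -0.44, with a deposited Cuffdiff p of 0.00415 and q of 0.108. The longer isoform was listed at 6.13 in 7wkWT, 5.36 in 7wkKO and 5.21 in 9wkKO. Among 24 tested PP2A subunits and regulators, 0 passed the deposited Cuffdiff test in either comparison, with 1 at an unadjusted p under 0.05 at 7 weeks and 2 from 7 to 9 weeks. The catalytic subunit gene Ppp2ca had FPKM of 121 and 131 at 7 weeks (q = 0.901) in the authors' deposited table.

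The first comparison asked how the samples labelled knockout differed from wild type at 7 weeks. Genes of the fetal and hypertrophic programme were higher in 7wkKO, with 15 of 24 tested members called higher and 0 called lower. In the authors' deposited table Acta1, the skeletal alpha-actin gene, rose from FPKM 198 to 1755 (log2 fold 3.15, q = 0.004995). The natriuretic peptide genes Nppa, from 416 to 2314 (log2 fold 2.48), and Nppb, from 208 to 608 (log2 fold 1.55), rose at the same q. Myh7, the beta-myosin heavy chain gene, rose from 15.7 to 57.2 (log2 fold 1.87), and Mybpc2 from 10.4 to 35.3 (log2 fold 1.76). The alpha-myosin gene Myh6 was listed at 5388 and 6000 (q = 0.992). Skeletal muscle markers, a list that also holds Acta1, had a median log2 fold of 1.06, with 2 of 8 called, Acta1 higher and Myl1 lower (from 58.6 to 40.6), and 5 when adjusted over the list alone (adjusted Fisher's exact p = 0.0693). The median log2 fold of the fetal and hypertrophy list was 0.85, at the 100th percentile of 10000 expression-matched random lists, and 15 members passed when adjusted over the list alone. Fisher's exact test of the calls gave a two-sided adjusted p of 1.06e-17 over the 34 lists tested. Of 13 tested markers of atrial muscle and conduction 6 were called higher, of which Nppa, Myl4 and Myl7 are also members of the fetal list (adjusted Fisher's exact p = 4.26e-06). Among the 6 were Sln from 31.7 to 70.8, Myl4 from 108 to 227 and Myl7 from 164 to 343 in the authors' deposited table.

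In all, 284 of 11987 tested genes were called at 7 weeks, 200 higher and 84 lower. Among genes with FPKM of at least 1 in both groups, other large rises in the authors' deposited table were those of Gdf15, a stress-induced cytokine gene, from 3.14 to 10.3, the transcription factor gene Myc from 2.33 to 7.21, Ankrd1 from 630 to 1775, Mybphl from 7.63 to 22.2, and Cnksr1 from 2.76 to 7.87. The largest falls among these genes were those of 2310039L15Rik from 6.78 to 2.04, Pfkfb1 from 4.09 to 1.43, Dok2 from 3.21 to 1.60, 2210407C18Rik from 11.4 to 5.79, and Fah from 12.8 to 6.54. The falls of Hspa1a, an inducible heat shock gene, from 15.3 to 8.20, Oas2, Tmem150c and Retnla followed. Extracellular matrix genes had 8 of 35 members called higher and 0 lower (adjusted Fisher's exact p = 1.38e-05), led by Thbs1 from 4.75 to 10.5 and Thbs4 from 3.57 to 7.58, and 10 passed when adjusted over the list alone. Fibroblast markers had 0 of 16 called by the deposited Cuffdiff test, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Their log2 fold was above 0 for 13 of 16, and their median of 0.16 stood at the 99.93rd percentile of matched random lists. It was 0.09, inside the central 95% of random lists, for the fibroblast markers held in no other list. Adrenergic and cAMP signalling had 4 of 24 called higher, namely Adra1a, Akap6, Pde3a and Adcy5 (adjusted Fisher's exact p = 0.0153), with 5 adjusted over the list alone. Immediate early genes had 3 of 19 called higher, Atf3, Ier5 and Cyr61, and 1 lower, Nr4a1 (adjusted Fisher's exact p = 0.00768), with 4 higher and 1 lower when adjusted over the list alone.

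In the authors' deposited table Atp2a2, the sarcoplasmic calcium pump gene, had FPKM of 2492 and 2681 (q = 0.981), Pln 2445 and 2473 (q = 0.994), and Ryr2 73.9 and 94.7 (p = 0.0526, q = 0.447). Of 31 calcium handling genes 2 were called higher, Sln and Cacna1h, and 2 passed when adjusted over the list alone (adjusted Fisher's exact p = 0.378). The median log2 fold of that list was 0.11, at the 99.94th percentile of matched random lists. Among 52 nuclear genes of oxidative phosphorylation 0 passed the deposited Cuffdiff test, with 5 at an unadjusted p under 0.05, while 48 had a log2 fold below 0 and the list median was -0.20. Endothelial markers likewise had 0 of 18 called, with 12 at an unadjusted p under 0.05 and 8 when adjusted over the list alone, and a median of -0.35. Their most abundant members in the authors' deposited table were Fabp4, at 2140 and 1545, and Aqp1, at 491 and 380. Interferon response genes had 1 of 23 called, Oas2 (from 4.32 to 2.38), and a median of -0.26, with 3 adjusted over the list alone. A normal p taken from the deposited test statistic, in place of the deposited p, left 14 genes called, and a threshold of 0.01 on q left 136.

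**Figure D1:**
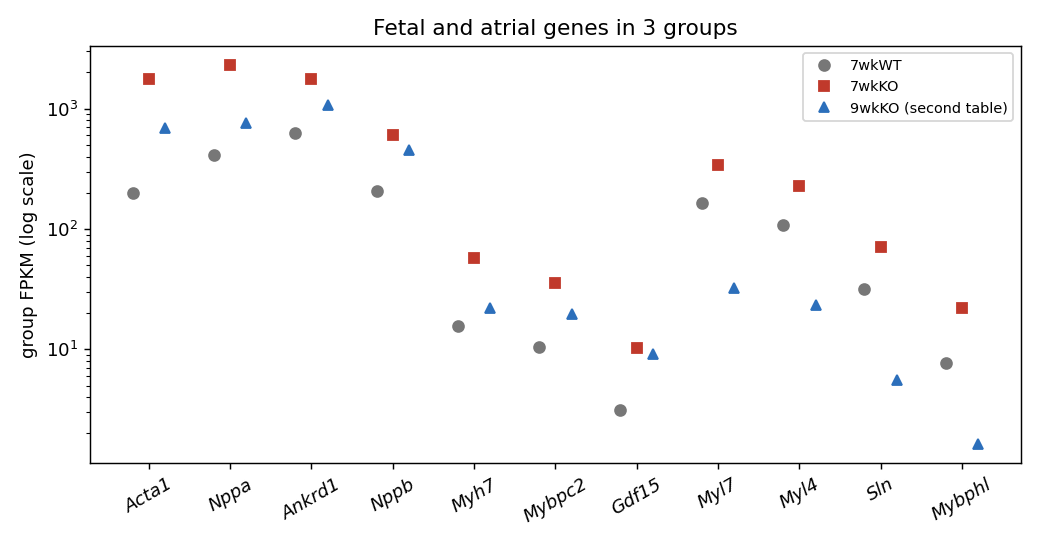
Group FPKM (log axis) of 11 fetal and atrial genes in 7wkWT (circles), 7wkKO (squares) and 9wkKO (triangles, from the second table), with 1 value per group and no error. Acta1 stood at 198, 1755 and 691, and Myl7 at 164, 343 and 32.5.

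The second comparison asked how the samples labelled knockout differed between 7 and 9 weeks. Age and any other difference between those 2 groups were not separated. Atrial and conduction markers fell, with 8 of 14 tested members called lower and 0 higher. Sln fell in the authors' deposited table from FPKM 71.4 to 5.51 (log2 fold -3.70, q = 0.00237), Myl7 from 345 to 32.5 (log2 fold -3.41), Myl4 from 229 to 23.2 (log2 fold -3.30), and Hcn4, a pacemaker channel gene, from 2.60 to 0.796. The list median was -0.63, 8 members passed when adjusted over the list alone, and the adjusted Fisher's exact p was 8.64e-07 over 35 lists. Fetal and hypertrophy genes had 8 of 24 called lower and 0 higher (adjusted Fisher's exact p = 6.51e-05), with 12 adjusted over the list alone. Of these called genes Nppa, Myl4 and Myl7 are in the atrial list as well, and the median of the fetal list, -0.44, was -0.23 when genes held in another list were left out. Acta1 fell in the authors' deposited table from 1764 to 691 (log2 fold -1.35, q = 0.00604), Nppa from 2327 to 767, Myh7 from 57.5 to 21.9, and Hamp from 11.7 to 0.703. Nppb, at 612 and 453 (q = 0.130), and Gdf15 (q = 0.898) were not called. Extracellular matrix genes had 13 of 35 called lower and 1 higher (adjusted Fisher's exact p = 6.32e-09), among them Fmod from 11.6 to 1.94 and Comp from 9.90 to 3.78, with 19 adjusted over the list alone. Skeletal muscle markers had 3 of 8 called lower and 0 higher (adjusted Fisher's exact p = 0.0150), Acta1, Myl1 from 40.9 to 27.1 and Pvalb from 2.04 to 0.353, with the same count over the list alone and a median of -0.45. Ion channel and gap junction genes had 3 of 22 called lower, Hcn4, Kcne1 and Kcnj3, and 2 higher, Kcnj2 and Scn4b (adjusted Fisher's exact p = 0.0128), with 6 lower and 3 higher over the list alone.

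Clock and hormone-responsive genes also differed between 7wkKO and 9wkKO. Any difference in collection time between these groups was not separated from age. The clock gene Arntl rose in the authors' deposited table from 0.406 to 1.57 (log2 fold 1.95), while Per2 fell from 14.4 to 5.68, Hlf from 14.5 to 8.37 and Per3 from 8.54 to 5.17. In all 7 of 18 clock genes were called, 2 higher and 5 lower (adjusted Fisher's exact p = 6.51e-05), and 9 passed when adjusted over the list alone. Glucocorticoid-responsive genes had 5 of 15 called lower and 1 higher (adjusted Fisher's exact p = 0.000202), with 10 adjusted over the list alone. Fkbp5 fell from 28.6 to 9.52 and Zbtb16 from 37.0 to 12.3, while Mt2 rose from 126 to 194 in the authors' deposited table. Immediate early genes moved both ways, with 3 of 20 called higher, including Fos from 1.80 to 4.12 and Egr1 from 5.86 to 11.2, and 5 called lower, including Atf3 from 11.6 to 4.46. Their adjusted Fisher's exact p was 1.88e-05, and 9 passed when adjusted over the list alone. Of 24 genes of the unfolded protein response and heat shock, 3 were called lower, Hspa1a, Hspa1b and Dnajb1, and 2 higher, Sdf2l1 and Pdia6 (adjusted Fisher's exact p = 0.0150), with 3 lower and 7 higher over the list alone. Interferon response genes had 5 of 23 called higher, among them Oasl2 from 4.92 to 7.30 (adjusted Fisher's exact p = 0.0140), with 11 adjusted over the list alone. Endothelial markers had 3 of 18 called higher, Cldn5 from 17.4 to 40.1, Kdr from 48.4 to 84.9 and Emcn from 39.9 to 57.1, with 9 higher and 1 lower, Rgcc (from 123 to 93.1), when adjusted over the list alone (adjusted Fisher's exact p = 0.1003).

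In this comparison 561 of 12046 tested genes were called, 228 higher and 333 lower. Among genes with FPKM of at least 1 in both groups, the largest rises in the authors' deposited table were those of Rnaset2b from 3.37 to 14.4, the chemokine gene Ppbp, Rrad from 54.5 to 168, and Ccl7, followed by Nepn, Efhd1, Ccl2, Apol10b, Cldn5 and Fos. Beside Sln, Myl7, Myl4 and Fmod, the largest falls among these genes were those of Mybphl from 22.3 to 1.64, Angptl7, the heat shock genes Hspa1b from 11.2 to 1.41 and Hspa1a from 8.27 to 1.42, Dkk3 and Sbk3. The calcium pump gene Atp2a2 had, in the authors' deposited table, FPKM of 2702 and 2630 (q = 0.997), Pln 2493 and 2504, Ryr2 95.4 and 83.6 (q = 0.842), and Myh6 6046 and 5004 (q = 0.991). Of 31 calcium handling genes 3 were called lower, Sln, Cacna1h and Cacna1g, and 0 higher (adjusted Fisher's exact p = 0.294), with 3 adjusted over the list alone. The median log2 fold of that list was -0.15, at the 0th percentile of matched random lists, with 19 members below 0 and 12 above. A normal p from the deposited test statistic left 69 genes called, 10 higher and 59 lower, and a threshold of 0.01 on q left 337.

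**Figure D2:**
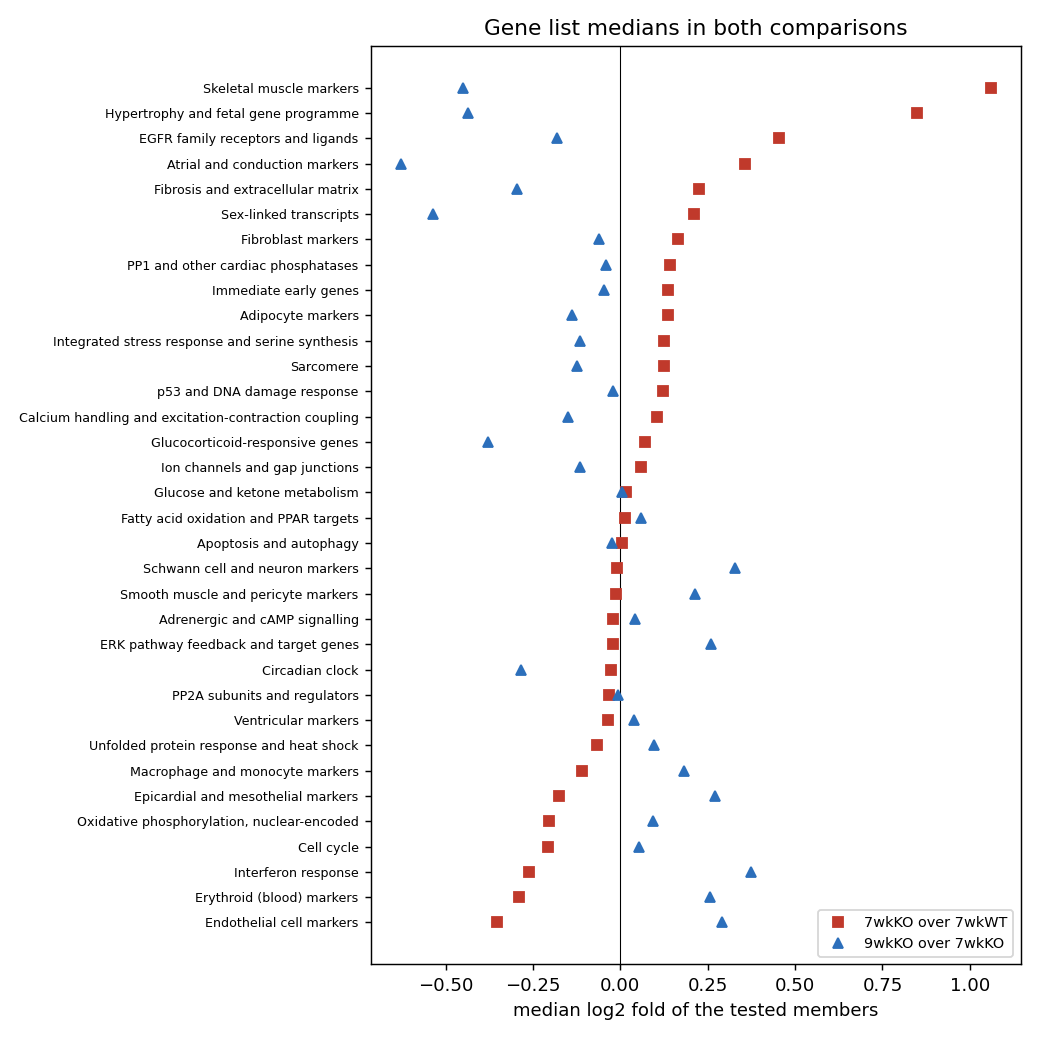
Median log2 fold of the tested members of each gene list in 7wkKO over 7wkWT (squares) and 9wkKO over 7wkKO (triangles). The fetal and hypertrophy list stands at 0.85 and -0.44 (-0.23 without genes held in another list), and the endothelial list at -0.35 and 0.29.

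Many genes called at 7 weeks moved the other way from 7 to 9 weeks. Of the 200 genes called higher at 7 weeks, 81 were then called lower and 2, Klhdc7a and H19, were called higher again. Of the 81 genes called lower at 7 weeks and tested in both comparisons, 21 were then called higher and 7 lower. Independent lists of the same sizes would share 5.59 genes called higher then lower and 1.49 called lower then higher. The largest summed changes among genes called higher then lower were those of Mybphl, Tmem163, Sln, Fgf12 and Cacna2d2. Among those called lower then higher they were those of Akap5, Slc41a3, Fah, Oas2 and Aplnr, and among those called lower in both, Hspa1b, Hspa1a, Tmem181b-ps, Adh1 and Tmem82. Both comparisons used the same 7wkKO samples, so their chance values are shared. With no effect in either comparison, 200 simulations gave at most 4 genes called higher then lower and at most 3 lower then higher. Few genes can pass either threshold without an effect, so these low counts were built in. They do not show how often shared 7wkKO values would reverse a gene that changed at 7 weeks. Over 11544 genes, which are not independent replicates, the log2 folds had a Pearson correlation of -0.46 across genes, and the simulations without any effect gave -0.47 on average. The folds had opposite signs in 66.6% of these genes, against 65.6% simulated (range 64.6% to 66.8%). The covariance was -0.0355, against a simulated -0.0170 (range -0.0183 to -0.0159). The groups could not be split, since they hold 1 value each, and the simulated values rest on the errors implied by the deposited p. The larger errors implied by the statistic alone were not simulated, and would give a simulated covariance larger in size. The level in 9wkKO relative to 7wkWT, set across 2 tables that were normalized separately and not tested, was above 7wkWT for 158 of the 200 genes called higher at 7 weeks. Those genes were chosen by the same 7wkWT values, which favours a level above them.

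**Figure D3:**
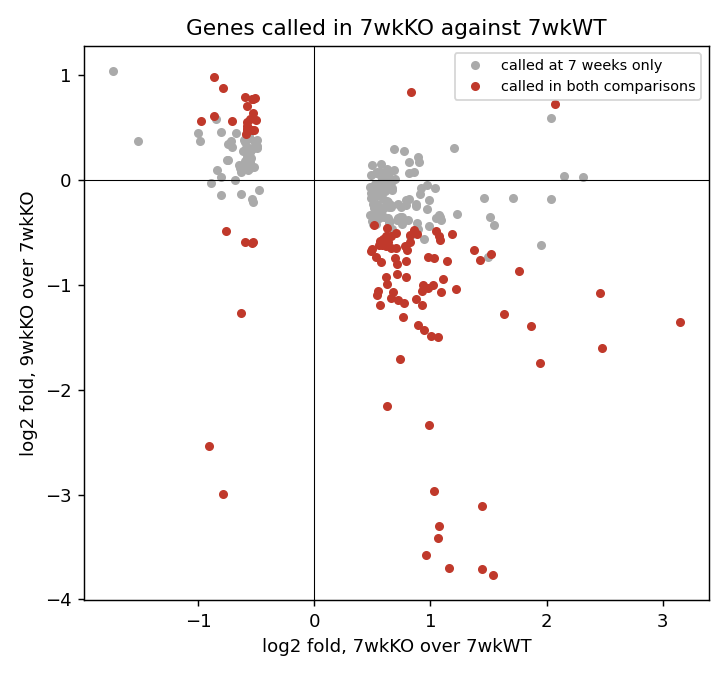
Log2 fold of each gene called at 7 weeks and tested in both comparisons, in 7wkKO over 7wkWT (horizontal) and in 9wkKO over 7wkKO (vertical), with genes called in both in red. Both comparisons share the 7wkKO samples. The red points hold 81 genes called higher then lower and 21 called lower then higher. Simulations with no effect gave at most 4 and 3, but few genes can pass without an effect, so these counts do not weigh the shared samples.

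At the isoform level, 220 of 15470 tested isoforms were called at 7 weeks, 156 higher and 64 lower, and 455 of 15531 from 7 to 9 weeks, 189 higher and 266 lower, in the authors' deposited tables. In 0 genes was 1 isoform called higher and another lower in either comparison. A change of at least 20 percentage points in the share of an isoform, which was not tested, was seen in 385 of 3535 genes with several isoforms at 7 weeks and in 319 of 3527 from 7 to 9 weeks. With a gene FPKM of at least 5 these counts were 136 and 85.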

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

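Scarna17, a small RNA gene that the authors did not test, was listed at 0 in 7wkWT, at FPKM 718.782 in 7wkKO and at 0 in 9wkKO, and stood out because, of these 3 groups, its listed value was above 0 in 7wkKO alone. A listed 0 does not show absence, since the tables hold no read counts. Snord16a, also not tested by the authors, was listed at 0 in 7wkWT, at FPKM 37.8 in 7wkKO and at 0 in 9wkKO.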

How the results depend on the processing

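The alternatives named here were set before the data were examined, except the count without atrial markers and the limits of 0.25 and 1 on the implied standard error. No value per sample was available, so leaving out each replicate was not run, and no paired analysis was possible because the tables carry no replicate values. At 7 weeks the count of 284 genes became 136 at q under 0.01, 430 at q under 0.10, 52 with a log2 fold of at least 1, 166 with FPKM of at least 10 in either group, and 14 with a normal p from the deposited statistic. From 7 to 9 weeks 561 became 337, 123, 256 and 69 under the same settings other than q under 0.10, which stayed within 1.5 times. All 14, and 68 of the 69, were among the genes called in the main count. The split of higher against lower calls moved from 70.4% higher to 79.4%, 64.7%, 90.4%, 66.9% and 100% at 7 weeks, in the order of settings above. From 7 to 9 weeks it moved from 40.6% higher to 36.5%, 23.6%, 40.2% and 14.5%. Recomputed adjustment, FPKM of at least 1 and isoform calls stayed within 1.5 times. The count without atrial markers (278 and 553) could not leave that range, since the atrial list held 6 and 8 called genes. It therefore does not weigh the atrial content of the samples. Isoform counts fell to 112 and 268 at q under 0.01, and the counts of isoform share changes to 136 and 85 at a gene FPKM of at least 5. The excess of the covariance over the simulated one was -0.0184, and became -0.0131 with FPKM of at least 1 in every group, -0.0113 with FPKM + 1, -0.0241 and -0.0127 with a smaller and a larger share of variance in 7wkKO, and -0.0146 with an implied error of at most 0.25. Every covariance setting used the errors implied by the deposited p, and the larger errors of the statistic alone were not simulated. The fewer genes or stricter rule account for the smaller counts by construction, and the cause was not tested for the others. Of the list medians under alternatives, 261 kept their side, while 7 lost and 7 gained a place outside the central 95% of random lists. The sign of 3 medians that had been inside that range turned when genes held in another list were left out. They were those of fatty acid oxidation and glucocorticoid-responsive genes at 7 weeks, which stayed inside it, and of ventricular markers from 7 to 9 weeks. The ventricular median then stood outside that range, at the 0.35th percentile. The 868 alternative values of the folds of named genes kept their direction where the gene was called, but this was largely fixed in advance. A pseudocount (217 values with FPKM + 1 and 217 with FPKM + 0.1) keeps the order of the 2 group values and can turn no fold. FPKM summed over isoforms (217 values) largely restates the gene value. Centring could turn no call, since the medians subtracted, -0.000613 and 0.0142, are smaller in size than the smallest called log2 folds, 0.48 and 0.42. Depth per sample is unknown, so what it limits was not tested.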

Other observations

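The tests of a shift of scale, of atrial share and of a return to the 7wkWT level were chosen after the result was seen, as was the limit on the implied error, while the gene lists, the comparison with simulated values and its shares of variance were planned. Further list members were called from 7 to 9 weeks in the authors' deposited table. Ventricular markers had 4 of 10 called lower (adjusted Fisher's exact p = 0.0039), Myh7, Irx2 from 4.12 to 2.02, Kcne1 from 6.04 to 3.16 and Lrrc10 from 189 to 101. Their median was 0.04, and -0.35 when genes held in another list were left out, which left 4 genes that moved both ways. Among macrophage markers Cx3cr1 rose from 0.587 to 1.64 and Cd14 from 4.83 to 7.64, while Lyve1 fell from 23.2 to 16.6, 3 of 15 in all (adjusted Fisher's exact p = 0.0702). The Y-linked genes Uty, from 2.68 to 1.67, and Eif2s3y, from 21.6 to 14.9, were called lower in 9wkKO, 2 of 5 sex-linked transcripts (adjusted Fisher's exact p = 0.0575). All 5 had a log2 fold below 0, with a median of -0.54 at the 0.03rd percentile of matched random lists, and 4 were lower when adjusted over the list alone. Whether 7wkKO and 9wkKO differ in sex makeup was not tested, since no value per sample was available, and it was not separated from age. Dbh, a gene of noradrenaline synthesis, fell from 1.63 to 0.561, the 1 call among 7 Schwann cell and neuron markers (adjusted Fisher's exact p = 0.414).

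The rise of fetal genes at 7 weeks was weighed against the authors' normalization and the makeup of the samples. The median log2 fold of all tested genes was -0.000613, below the lowest of the 12 called fetal genes outside the atrial list, 0.53. The called fetal genes thus rose relative to the typical tested gene. FPKM is scaled to the number of mapped fragments, so such a median can follow from the scaling itself and cannot decide on a shift of scale. Those 12 genes had a median log2 fold of 1.29, and the 6 atrial genes called in both comparisons had 1.07, with a range of 0.74 to 2.48 (Nppa, itself a fetal gene, then Sln at 1.16), so a larger atrial share in 7wkKO stays open as a source for part of the rise. In 9wkKO the 12 genes lay above 7wkWT, with a median of 0.70 across tables and the lowest, Ctgf, at 0.02. They were chosen as called over the same 7wkWT values, which favours levels above 7wkWT, and no error was set for these levels. The 10 tested atrial genes outside the fetal list, not chosen by a call, had a median of -0.44 with an upper quartile of -0.33. That argues against a larger atrial share than in 7wkWT as the source there.

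The fall of atrial genes from 7 to 9 weeks may reflect less atrial tissue in the 9wkKO samples. That explanation needs ventricular markers not to be lower, and their median was 0.0395 over the 8 outside the fetal and atrial lists, but -0.35 over the 4 held in no other list. Those 4 moved both ways, with Irx4 (0.36) and Hey2 (0.20) higher and Irx2 (-1.03) and Lrrc10 lower. The explanation therefore stays open. Of the 6 atrial genes called higher at 7 weeks, 3 lay below 7wkWT in 9wkKO by over 2 errors, Sln, Myl7 and Myl4. Their log2 levels across tables were -2.54 to -2.22, each at least 4.40 errors from 0, which argues against a return of the whole set to the 7wkWT level. By chance 0.137 of 6 independent genes would lie below by over 2 errors. These genes are not independent and the 3 fell by similar amounts, so that expected count adds no support. A return of some members stays open, as Hcn4 (-0.97), Pam (0.37) and Nppa (0.87) lay within 2 errors. A change with age or with the knockout is untested, since the 9wkWT samples were not analysed here.

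The reversal between comparisons could come from chance values of the shared 7wkKO samples. The covariance of the folds was 2.08 times the simulated one, and 1.56 to 3.13 times over the alternatives. All of these settings used the errors implied by the deposited p. The errors implied by the statistic alone, about 1.74 times as large, were not simulated. They would give a simulated covariance larger in size, so the excess may not hold with them. The correlation of -0.46 was no stronger than the simulated -0.47 of the main setting. It was stronger than the -0.31 simulated with a smaller share of variance in 7wkKO, and weaker than the -0.62 simulated with a larger share. The counts were 81 called higher then lower and 21 lower then higher, against at most 4 and 3 simulated with shared samples and no effect. Those simulated counts are low by construction, since few genes pass without an effect, so the counts do not weigh this source. The covariance exceeded the one simulated with the errors implied by the deposited p, but those errors and the shares of variance were assumed. How much of the reversal comes from the shared samples therefore stays open, and 1 unusual 7wkKO sample was not testable without values per sample.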
